A study of Mus musculus with 4 samples.

How the data were processed

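Messenger RNA was sequenced from 4 cultures of immortalised mouse mesenchymal stem cell lines: clone 6 and clone 12, each carrying either an empty retrovirus (vector, n = 2) or a retrovirus for Flag-HA-tagged NR6A1 (n = 2). The values deposited by the authors are FPKM (fragments divided by transcript length and by the number of mapped fragments), 1 value per gene and library, for 21881 gene symbols with no symbol repeated. Per the submitters' processing notes, TopHat 1.2.0, Cufflinks 1.0.3 and the mouse build mm9 were used; the gene annotation and any strand setting are not given in the sources used here. Per the labels' protocols, the RNA was column-purified and DNase-treated, and polyadenylated RNA went into a standard Illumina library. Cufflinks divides the fragments of a gene by an effective length, which is very small for short genes, so a few reads on a small nucleolar RNA or a microRNA gene give a large FPKM. Reads of overlapping or near-identical genes can be shared between them in such values, and FPKM of Nr6a1 sums any reads of the retrovirus and of the cell's own gene.

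No read counts were used here, so depth was inferred from the steps between low FPKM values. Over 9377 genes with 1 annotated transcript length of at least 1500 bases, the value of 1 read was taken as inversely proportional to the length minus 210 bases, a shift found from the data. Among values under 10 inferred reads, 49.2% to 51.0% lay within 0.1 of a whole read, against 20% by chance, so the depths are estimates and no count test was run on them. They were 24.5 and 23.1 M (1e6) mapped reads for the vector libraries of clone 6 and clone 12, and 21.2 and 20.6 M for the NR6A1 libraries. At these depths 1 FPKM on a transcript of 2000 bases stood for 36.9 to 43.8 reads. Transcript lengths and GC content came from GENCODE transcripts, and older symbols from RefSeq genes, of a later mouse assembly, used for no coordinates. Of the 21881 symbols, 21642 matched the RefSeq names.

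Values were tested as log2(FPKM + 1) for the 11346 genes with a mean of at least 1 FPKM over the 4 libraries. Fold changes below are on that scale, which understates the change of low genes. The test was limma 3.58.1 in R 4.3.3, two-sided, with a mean-variance trend, virus as the contrast and clone as a block, and Benjamini-Hochberg adjustment over all genes tested at 0.05. The block was taken from the treatment protocol, in which each line received both viruses, so libraries of the same number come from the same cell line. As a check of this pairing, the difference between clone 6 and clone 12 correlated across genes between vector and NR6A1 libraries with r = 0.628 (0.874 without short RNA genes); genes are not independent replicates. The model left 1 residual degree of freedom and drew on the spread of all genes through a prior of 2.9 degrees of freedom. The labels call the 2 clones independent lines and name no further cultures, so a p-value measures how alike the 2 lines differed between viruses and not the spread between repeat cultures.

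Gene lists for 34 pathways, cell types and gene families were fixed, and the 28 with at least 5 tested members were compared with all other genes by camera with a preset correlation of 0.01, with adjustment over the lists. Camera with an estimated correlation and fry stood beside it, and counts of members past the threshold were also made with adjustment over the list alone. Each list's median change was set against 10000 random lists of the same size matched on mean expression in 20 bins. The named genes were Nr6a1; the 12 highest and 12 lowest changes among genes past the threshold and of one direction in both clones or, as fewer than 5 passed in each direction, the 12 genes per direction with the largest smaller-of-both-clones change and a mean of at least 5 FPKM; in each list up to 6 members past the threshold or otherwise up to 4 with the highest mean FPKM; and the 3 highest and 3 lowest for clone 12 against clone 6. Other genes named were chosen after their values were seen. Single values of some genes are not reported here. The test, the lists, the naming rule and these alternatives were chosen before the data were examined: pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, upper quartile and quantile scaling, no variance trend, a robust prior, no clone block, each library left out, a false discovery rate of 0.1, and other size thresholds. Chosen after seeing the data were the removal of the 198 tested short RNA genes (microRNA, small nucleolar, small Cajal body and small nuclear RNA genes), the removal of a GC and length trend, the let-7 list without Nr6a1, and the counts of list members between clones.

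The test was run on simulated data with 200 changed genes in 20 runs. With all 11346 genes it recovered 65.1% of 2-fold, 91.9% of 4-fold and 97.7% of 16-fold changes, and 6.03% of its calls were false. With the 11148 genes left without short RNA genes it recovered 87.7%, 99.6% and 100%, with 8.43% false. For lists shifted by 0.3 log2 units, the preset correlation called 40 of 40 shifted and 3 of 520 unshifted lists, and the estimated correlation called 0 of 40. The simulated genes varied independently of each other. In the data the estimated correlation within a list reached 0.681 (glycolysis and hypoxia genes). The simulation thus cannot give the rate of false list calls in these data. Its recovery rates hold for 200 changed genes of these sizes, with spreads drawn from the fitted prior. They do not give the share of changed genes found in these data, where the fit over all 11346 genes called 4. Figures were drawn with matplotlib 3.10.9.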

Results

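The data were FPKM values of 4 mRNA libraries from mesenchymal stem cell lines of adult mouse bone marrow, fibroblast-like cells that can form bone, fat and cartilage. Clone 6 and clone 12, both with an intact Dicer gene, each contributed 1 library with an empty retrovirus and 1 with a retrovirus for NR6A1, so each group held 2 libraries. NR6A1, also called GCNF, is an orphan nuclear receptor of the embryo and germ line known mainly as a repressor. The series title places Nr6a1 among the genes that the let-7 microRNAs hold down in adult fibroblasts. The inferred depth was 24.5 and 23.1 M mapped reads for the vector libraries of clone 6 and clone 12, and 21.2 and 20.6 M for the NR6A1 libraries (M, 1e6). Between 15718 and 15979 genes were above 0 in a library. Log values of the same clone correlated across genes with r = 0.966 (clone 6) and 0.968 (clone 12) between viruses, and values of different clones with 0.913 to 0.936.

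The first comparison asked which genes differ when NR6A1 is raised in adult cells. Nr6a1 itself was at 4.18 and 2.80 FPKM in the vector libraries of clone 6 and clone 12 and at 783 and 598 FPKM in the NR6A1 libraries. Its mean was 3.49 ± 0.973 FPKM with vector and 690.1 ± 131 with NR6A1 (SD, n = 2), and it rose by 7.27 ± 0.07 log2 units (SE, limma adjusted p = 0.000488). The rise was 7.24 in clone 6 and 7.30 in clone 12. Reads of the virus and of the cell's own gene were not told apart in these values. With any 1 library left out, which also removes the clone block, the change stayed at 7.05 to 7.49 but limma called no gene (adjusted p of Nr6a1 0.106 to 0.366; 96 to 286 genes at an unadjusted p under 0.05).

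Of the 48 genes other than short RNA genes that differed at least 2-fold in the same direction in both clones, 44 were lower with NR6A1. The protein-coding genes that follow were taken by the naming rule. Sfrp2, a secreted modulator of Wnt signalling, was at 1310 and 352 FPKM in the vector libraries of clone 6 and clone 12 and at 204 and 29.0 in the NR6A1 libraries, a log2 change of -3.12 ± 0.23 (SE). Npr3, the clearance receptor of natriuretic peptides, stood at 21.2 and 22.3 against 1.91 and 0.792 FPKM (-3.32 ± 0.22). Phospho1, a phosphatase of matrix vesicles that starts bone mineral formation, stood at 70.1 and 14.5 against 13.7 and 0.0913 FPKM (-3.05 ± 0.40). Osgin1, a growth inhibitor induced by oxidative stress, stood at 12.2 and 10.9 against 1.16 and 0.497 FPKM (-2.80 ± 0.15).

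Further genes lower in both clones were the cell-surface proteoglycan Sdc3 (log2 change -2.76 ± 0.40), the endoplasmic reticulum protein gene Fam134b (-2.15 ± 0.14), Fam20a, a pseudokinase gene needed for enamel (-1.98 ± 0.13), the extracellular superoxide dismutase Sod3 (-1.85 ± 0.11) and the cytokine gene Clcf1 (-1.84 ± 0.08). Higher in both clones were Capn6, a calpain without protease activity (1.74 ± 0.18), and the contractile genes Tagln (1.26 ± 0.12) and Actg2 (1.08 ± 0.08). Tagln, which encodes the actin-binding protein transgelin, was at 102 and 25.7 FPKM with vector and 216 and 71.9 with NR6A1, and the smooth muscle actin gene Actg2 at 39.9 and 2.71 against 85.8 and 6.78. None of these 12 genes passed the threshold over all genes tested, where their limma adjusted p ran from 0.0624 (Clcf1) to 0.262 (Sdc3). Without short RNA genes 11 of the 12 passed, with adjusted p from 0.0116 to 0.0482, and Sdc3 had 0.0603. The size of the change depended on the pseudocount: with 0.1 and 5 in place of 1 it was -4.03 and -2.08 for Npr3, -4.30 and -1.97 for Phospho1, -3.75 and -1.51 for Osgin1, -2.96 and -1.02 for Sod3, and 2.36 and 1.01 for Capn6. Over all the other settings with 4 libraries the adjusted p of the 12 genes ran from 0.00767 to 1.

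**Figure D1:**
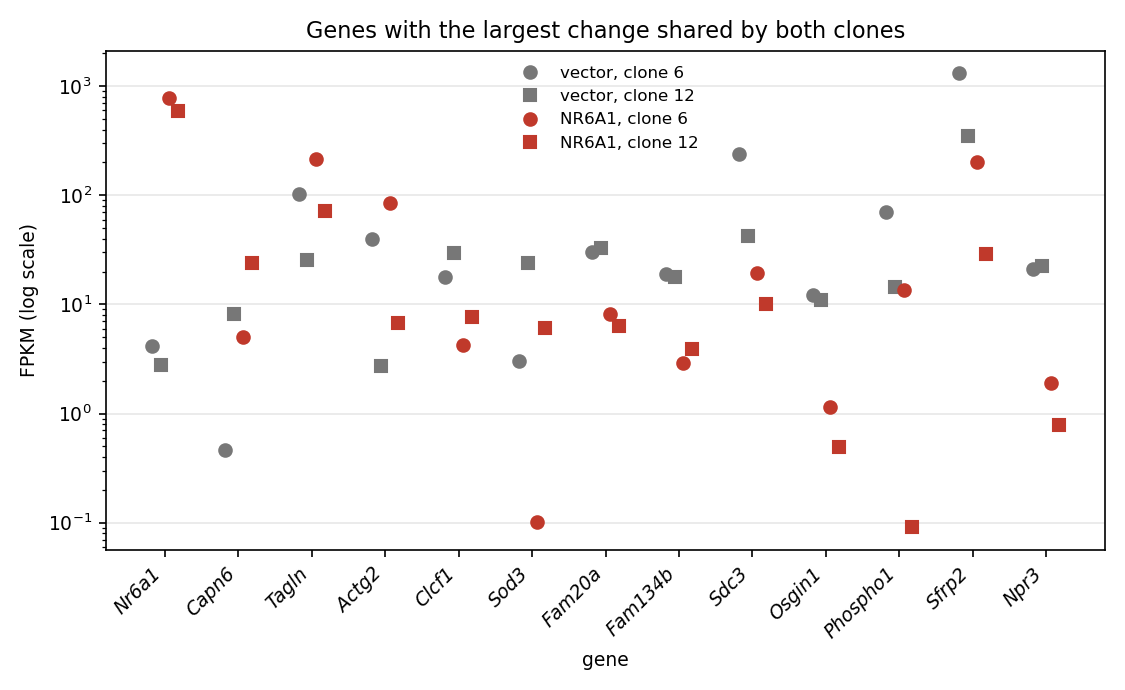
FPKM per library (log axis) of Nr6a1 and the 12 protein-coding genes taken by the naming rule, which picks per direction, in order of log2 change; grey points are vector and red points NR6A1 libraries, circles clone 6 and squares clone 12. Nr6a1 lies at 2.80 to 4.18 FPKM with vector and 598 to 783 with NR6A1, and for each other gene both clones shift the same way, as the rule requires.

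Over all 11346 genes tested, 4 passed the threshold, 3 higher (Nr6a1, Snord72, Mir1907) and 1 lower (Snord91a), and 962 had an unadjusted p under 0.05 (394 higher, 568 lower, 8.48% of the genes). The 3 besides Nr6a1 are short RNA genes read in 1 group and listed at 0 in the other. Snord72, a small nucleolar RNA, had 218 and 225 FPKM with NR6A1 (limma adjusted p = 0.000488), Mir1907, a microRNA, had 35.0 and 35.9 with NR6A1 (0.00358), and Snord91a, also a small nucleolar RNA, had 110.4 and 115 with vector (0.000760). The same naming rule took 8 more short RNA genes, none past the threshold: Snord69, Snora75, Snora23, Snora78, Snora30 and Snord1c were higher, and Mir2861 and Scarna8 lower, in both clones. Without the 198 short RNA genes, a choice made after seeing the data, 52 genes passed, 10 higher and 42 lower. Of these, 41 changed at least 2-fold (36 lower, 5 higher). All 52 had one direction in both clones, which passing requires, since the residual of this fit is the difference between the clones' changes. A robust prior, planned beforehand, gave 38 genes (10 higher, 28 lower), of which 31 were among the 52 and 7 were short RNA genes.

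Of the 52 genes, the following were named after their values were seen. Alpl, the alkaline phosphatase of bone, was at 509 and 18.2 FPKM with vector and 228 and 6.85 with NR6A1 (log2 change -1.22 ± 0.08). Wnt10b, a Wnt ligand, was at 40.9 and 25.7 against 22.4 and 13.0 FPKM (-0.88 ± 0.08), and Ly6a, the stem cell antigen Sca-1, at 18.98 and 317 against 9.31 and 125 (-1.14 ± 0.12). The metabolic genes Acadm, of fatty acid oxidation (-1.03 ± 0.11), Pdk4, which inhibits pyruvate dehydrogenase (-1.30 ± 0.12), and Aldh2, an aldehyde dehydrogenase (-0.93 ± 0.11), were also lower. Osr1, a transcription factor of embryonic mesenchyme, changed by -1.04 ± 0.12 and the peptidase gene Mme by -2.03 ± 0.26. On the higher side stood the collagen gene Col3a1 (0.70 ± 0.07), the protease inhibitor gene Timp3 (0.81 ± 0.07), the matrix gene Smoc2 (1.14 ± 0.13), Dkk3 (0.68 ± 0.07) and the myosin light chain gene Myl9 (0.67 ± 0.07).

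Smooth muscle and contractile genes were higher with NR6A1 as a group. Of 18 tested, 15 were higher in both clones and none lower in both, with a median log2 change of 0.31 in clone 6 and 0.26 in clone 12. Acta2, smooth muscle alpha actin, was at 625 and 194 FPKM with vector and 960.2 and 332 with NR6A1, and the tropomyosin gene Tpm1 at 635 and 718 against 735 and 773. The list passed camera with the preset correlation (median 0.30, adjusted p = 2.65e-09) and not with an estimated one (p = 0.0917, adjusted p = 0.839 with an estimated correlation). In the simulation the estimated correlation called 0 of 40 shifted lists, so not passing it decides nothing, here and for the lists below. No member passed over all genes tested, 10 passed adjusted over the list alone (all higher), and 3 passed without short RNA genes (Tagln, Actg2, Myl9). In fits that left out the vector library of clone 12 or the NR6A1 library of clone 6 the call was lost (median 0.06 and 0.03); such fits have no clone block.

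Cholesterol synthesis genes were lower with NR6A1 in both clones. Of 19 tested, 17 were lower in both clones, with a median log2 change of -0.32 in clone 6 and -0.22 in clone 12. Hmgcs1, a member not tested, was listed at 0 in every library. Whether it was not expressed or not quantified cannot be told from these values. Fdps, which makes farnesyl diphosphate, was at 152 and 203 FPKM with vector and 101.5 and 154 with NR6A1, Idi1, an isomerase of the same pathway, at 92.3 and 113 against 54.0 and 88.5, and Sqle, squalene epoxidase, at 103 and 126 against 76.9 and 105. Srebf2, the transcription factor of the pathway, was at 111 and 121 against 104 and 115 FPKM. The list passed with the preset correlation (median -0.32, adjusted p = 1.17e-09) and not with an estimated one (p = 0.0882, adjusted p = 0.839 with an estimated correlation). No member passed over all genes tested, and 8 passed adjusted over the list alone, all lower. With any 1 library left out, in fits without a clone block, the list kept its direction and call, while its median ran from -0.45 to -0.11 (adjusted p of at most 0.032).

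Osteoblast genes were lower with NR6A1 as a group. Of 16 tested, 9 were lower and 2 higher in both clones, with a median log2 change of -0.34 in clone 6 and -0.14 in clone 12, a difference between clones that was not tested. In clone 6, 13 were lower and 3 higher, 7 of the lower by at least 1.5-fold. In clone 12, 10 were lower and 5 higher, 2 of the lower by at least 1.5-fold. The 4 most abundant members did not move together: Col1a2 was at 1935 and 870 FPKM with vector and 1273 and 897 with NR6A1, Sparc at 1280 and 1062 against 1184 and 1067, Col1a1 at 1547 and 522 against 1422 and 693, and Spp1 at 254 and 1794 against 409 and 1157. The list passed with the preset correlation (median -0.26, adjusted p = 0.0116) and not with an estimated one (adjusted p = 0.839 with an estimated correlation), and it lost its call without the clone block (adjusted p = 0.371) and with no filter (median -0.23, adjusted p = 0.228). Its median turned to 0.76 without the vector library of clone 6 and to 0.0082 without the NR6A1 library of clone 12. No member passed over all genes tested, 2 lower (Alpl and the homeobox gene Dlx5) and 1 higher (the matrix gene Postn) passed adjusted over the list alone, and Alpl passed without short RNA genes.

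Immediate early genes, the fast response to serum and stress, had a median log2 change of 0.39 in clone 6 and -0.0018 in clone 12, a difference between clones that was not tested. Of 22 tested, 8 were higher and 1 lower in both clones. Cyr61, a matrix signalling gene, was at 378 and 446 FPKM with vector and 543 and 576 with NR6A1, and Junb, an AP-1 subunit gene, at 91.1 and 186 against 86.1 and 183. The list passed with the preset correlation (median 0.21, adjusted p = 0.000636) and not with an estimated one (adjusted p = 0.839 with an estimated correlation); the call was lost without the vector library of clone 6 (median -0.36) or the NR6A1 library of clone 12 (-0.06). Of the 20 p53 targets tested, 11 were higher and 3 lower in both clones, with a median of 0.13 (adjusted p = 0.0318 with the preset and adjusted p = 0.839 with an estimated correlation); the call was lost without the clone block (adjusted p = 0.0631), under both other filters (0.199 and 0.106), and without the vector library of clone 12 (median -0.04) or the NR6A1 library of clone 6 (0.0026). Plk2, a kinase gene of this list, was at 20.7 and 71.3 FPKM with vector and 53.8 and 96.1 with NR6A1, and Mdm2, which encodes the p53 ubiquitin ligase, at 50.7 and 186 against 54.5 and 140.2. No immediate early gene and no p53 target passed, over all genes tested or adjusted over the list alone.

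**Figure D2:**
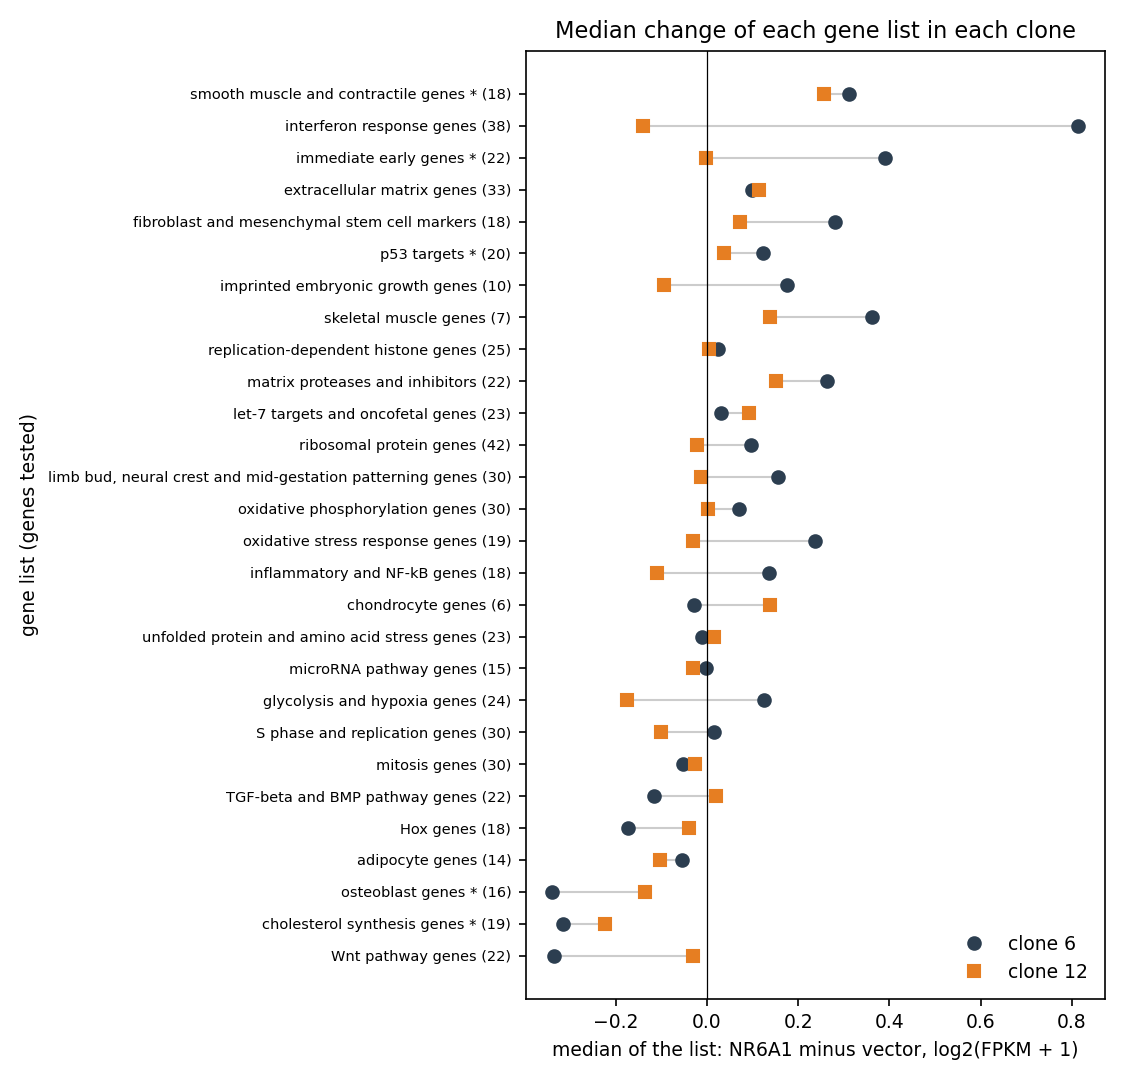
Median log2 change with NR6A1 of the 28 tested gene lists (number of genes tested in brackets), 1 point per clone, clone 6 as circles and clone 12 as squares; an asterisk marks the 5 lists past the threshold with the preset correlation. Contractile genes (0.31 and 0.26) and cholesterol synthesis genes (-0.32 and -0.22) lie on one side of 0 in both clones, and interferon response genes on both sides (0.81 and -0.14).

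The let-7 targets and oncofetal genes, the list nearest to the series title, did not pass as a group. Of 23 tested, 10 were higher and 4 lower in both clones, with a median log2 change of 0.06 (adjusted p = 0.116), and without Nr6a1 the adjusted p was 0.38. In fits with 1 library left out and no clone block, Nr6a1 was kept in the list. The list's median was then 0.15 without the vector library of clone 6 and 0.16 without the NR6A1 library of clone 12. It was -0.0156 and 0.0060 without the other libraries. Nr6a1 was the 1 member past the threshold, over all genes tested and adjusted over the list alone. Hmga2, a chromatin protein gene and let-7 target named after its values were seen, was at 12.4 and 24.2 FPKM with vector and 29.0 and 29.0 with NR6A1, and the RNA-binding protein gene Igf2bp1 at 3.30 and 2.60 against 3.18 and 2.96. Lin28a and Lin28b, which block let-7 processing, were at 0.00151 FPKM or less in every library. Hox genes, which pattern the body axis, were tested for 18 members, all of the A and C clusters, with 5 higher and 11 lower in both clones and a median of -0.10 (adjusted p = 0.17). Hoxc6 alone passed adjusted over the list alone, at 5.55 and 7.81 FPKM with vector and 2.48 and 3.01 with NR6A1, while Hoxa11 was at 36.3 and 24.3 against 34.2 and 22.9.

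Of the pluripotency genes only Klf4, Klf5 and Dnmt3b reached the filter, Klf4 at 24.0 and 24.3 FPKM with vector and 10.7 and 19.3 with NR6A1 (adjusted p = 0.548). Pou5f1, which NR6A1 represses in the embryo, was at 0.0358 FPKM or less in every library, about the level of 1 read, so a decrease was not detectable at this depth. None of the 29 germ cell genes on the fixed list reached the filter, and their highest value was 1.62 FPKM (Sycp3). Germ cell genes outside the list were not examined as a group. Of them, the oocyte genes Mos and Oog1, named after their values were seen, were lower in both clones. Mos, 1 of the 52 genes, was at 14.1 and 8.66 FPKM with vector and 6.47 and 3.47 with NR6A1. Oog1 was at 1.61 and 3.65 against 0.227 and 1.06 FPKM. These 2 genes give no direction for germ cell genes as a class. Limb bud, neural crest and mid-gestation patterning genes had 30 members tested, 11 higher and 8 lower in both clones, and a median of 0.04 (adjusted p = 0.38). Osr1 was the 1 member that passed adjusted over the list alone, and Snai2, a repressor of the neural crest, was at 67.7 and 45.9 FPKM against 83.8 and 52.1. For imprinted growth genes the median over 10 tested was 0.13 (adjusted p = 0.256), with Gnas at 776 and 697 FPKM against 861 and 724.

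Interferon response genes were higher with NR6A1 in clone 6 and slightly lower in clone 12, with median log2 changes of 0.81 and -0.14 over 38 genes. Bst2, the antiviral membrane protein tetherin, was at 138 and 836 FPKM with vector and 259 and 677 with NR6A1, while B2m, the light chain of class I molecules, was at 1345 and 1473 against 1340 and 1556. The list did not pass (median 0.29, adjusted p = 0.0971) and passed without short RNA genes (adjusted p = 0.0449), though not with an estimated correlation (adjusted p = 0.829 with an estimated correlation). With 1 library left out, in fits without a clone block, its median turned direction, from -0.834 without the vector library of clone 6 to 1.412 without that of clone 12. Inflammatory and NF-kB genes (18 tested) had a median of 0.03, 0.14 in clone 6 and -0.11 in clone 12 (adjusted p = 0.464), with the chemokine gene Ccl2 at 39.3 and 278 FPKM with vector and 64.5 and 255 with NR6A1. Glycolysis and hypoxia genes (24 tested) had a median of -0.02, 0.12 in clone 6 and -0.18 in clone 12 (adjusted p = 0.601), with the pyruvate kinase gene Pkm2 at 910.4 and 1592 against 884 and 1218. No member of these 3 lists passed, over all genes tested or adjusted over the list alone.

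Of the remaining lists, none passed with the preset correlation. Fibroblast and mesenchymal stem cell markers (18 tested) had a median of 0.13 (adjusted p = 0.0971), with Vim at 1964 and 2211 FPKM against 2404 and 2388; adjusted over the list alone 3 were higher and 1 lower. Extracellular matrix genes (33 tested) had a median of 0.14 (adjusted p = 0.121; 3 higher and 3 lower adjusted over the list alone) and matrix proteases and inhibitors (22 tested) one of 0.06 (adjusted p = 0.0971; also 3 and 3). Wnt pathway genes (22 tested) had a median of -0.32, -0.34 in clone 6 and -0.03 in clone 12 (adjusted p = 0.121), and adjusted over the list alone 2 were higher and 4 lower. TGF-beta and BMP pathway genes (22 tested) had a median of -0.05 (adjusted p = 0.832; 1 higher and 1 lower adjusted over the list alone). The cell cycle lists, S phase (30 tested, median -0.02, adjusted p = 0.224) and mitosis (30 tested, median -0.04, adjusted p = 0.121), had no member past the threshold, adjusted over the list alone or over all genes.

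Adipocyte genes (14 tested) had a median of -0.11 (adjusted p = 0.38), with the fatty acid binding protein gene Fabp4 at 285 and 79.4 FPKM against 129 and 73.3. The median was 0.01 for chondrocyte genes (6 tested, adjusted p = 0.587) and 0.10 for skeletal muscle genes (7 tested, adjusted p = 0.108), of which 2 were higher adjusted over the list alone. It was 0.0045 for unfolded protein and amino acid stress genes (23 tested, adjusted p = 0.72), 0.03 for oxidative stress response genes (19 tested, adjusted p = 0.464) and 0.05 for ribosomal protein genes (42 tested, adjusted p = 0.111). Oxidative phosphorylation genes had 0.04 (30 tested, adjusted p = 0.502) and replication-dependent histone genes 0.06 (25 tested, adjusted p = 0.601), a class poorly captured from polyadenylated RNA. MicroRNA pathway genes (15 tested) had a median of 0.0042 and a mean of -0.02, and camera's direction was down (adjusted p = 0.72). Except for the 2 skeletal muscle genes, no member of these lists passed adjusted over the list alone. With an estimated correlation none of the 28 lists passed, the lowest adjusted p being 0.839. As that correlation also called 0 of 40 shifted lists in the simulation, this does not tell changed lists from unchanged ones. Fry called none by direction and 5 in either direction (let-7, fibroblast, contractile, S phase and Wnt genes, adjusted p = 0.0454 each). The let-7 list held Nr6a1 itself in the fry test.

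Markers of other cell types were few and low in all 4 libraries. Blood cell markers had 4 members above the filter, the highest being the monocyte gene Cd14 at 8.35 FPKM. Endothelial markers had 2, Egfl7 and Eng, a gene that mesenchymal cells also express (43.5 to 55.4 FPKM). Neural markers had 4, with Ncam1 at 11.2 and 17.8 FPKM with vector and 15.5 and 23.2 with NR6A1; adjusted over the list alone 2 were higher and 1 lower. The 1 epithelial marker above the filter, the keratin gene Krt14, was at 12.9 and 1.5 FPKM with vector and 0.615 and 0.298 with NR6A1 (adjusted p = 0.521 over all genes).

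How far both clones responded alike was described gene by gene, without a test across libraries. Among the 11148 genes without short RNA genes, 229 differed by at least 1 log2 unit between viruses in clone 6 and 114 in clone 12. Of these, 48 differed in both with the same sign (4 higher, 44 lower), against 0.125 and 1.25 for independent lists, and 7 with opposite signs, against 0.969. Capn6, Tagln and Actg2 were with Nr6a1 the 4 shared higher genes. The changes of both clones correlated across genes with r = 0.401 and rho = 0.274, and r was 0.369 without Nr6a1; genes are not independent replicates. Over all genes tested, short RNA genes included, 301 and 191 genes differed, 60 with the same sign and 22 with opposite signs, and r was 0.134.

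**Figure D3:**
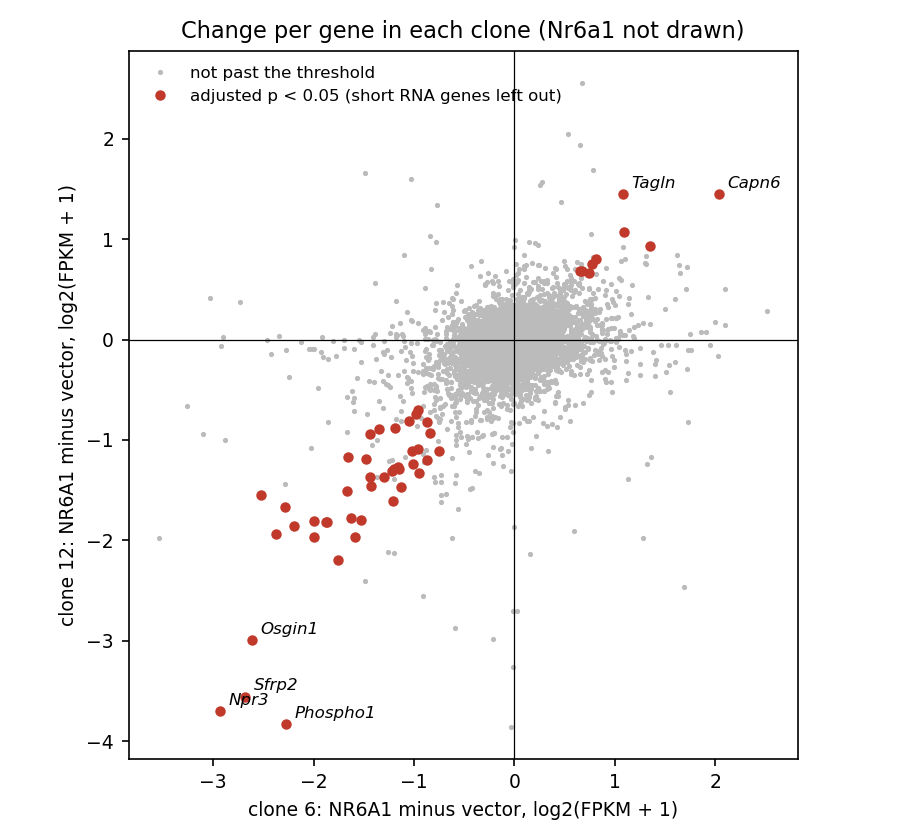
Change of log2(FPKM + 1) from vector to NR6A1 in clone 6 (x axis) and clone 12 (y axis), 1 point per gene tested, short RNA genes and Nr6a1 left out; red points passed the threshold once short RNA genes were left out. The red points lie in the lower left (42 genes) and upper right (9 genes without Nr6a1), as passing this fit requires, and the lowest are Npr3, Sfrp2, Phospho1 and Osgin1.

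The second comparison set clone 12 against clone 6 and gives the size of differences between lines that virus effects stand beside. The clones differed in interferon response and in bone-forming genes. Of 38 interferon response genes tested, 34 were higher in clone 12 and none lower, with a median log2 difference of 1.98; Isg15, a ubiquitin-like antiviral protein gene, was at 30.9 FPKM in clone 6 and 347 in clone 12 with vector. Of 16 osteoblast genes, 10 were lower and 3 higher in clone 12, with a median of -1.24; Sp7, the osteoblast transcription factor also called osterix, was at 120.1 against 0.459 FPKM with vector and Alpl at 509 against 18.2. Among contractile genes 11 of 18 were lower and none higher in clone 12, and among inflammatory and NF-kB genes 10 of 18 were higher and none lower. Isg15, Sp7 and Alpl were named here after their values were seen.

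By the naming rule, Cxcl5, a neutrophil chemokine gene, was at 0.0941 FPKM in clone 6 and 73.0 in clone 12 with vector, and at 0.553 and 91.9 with NR6A1 (log2 difference 5.99 ± 0.10, limma adjusted p = 0.00157). Fmod, which encodes the collagen-binding protein fibromodulin, was at 357 against 1.55 FPKM with vector and 193 against 1.10 with NR6A1 (-6.83 ± 0.17, adjusted p = 0.00268). The other 4 genes taken by the rule were short RNA genes listed at 0 in one clone: Snord99 and Mir1949 in clone 6, Snord57 and Snord11 in clone 12. Over all genes 2490 passed the limma threshold, 1302 higher and 1188 lower in clone 12, and 3492 passed without short RNA genes. The median absolute log2 difference over all genes was 0.22 between clones and 0.10 between viruses. With no filter on low values limma called 0 genes between clones (5360 at an unadjusted p under 0.05), and in fits on 3 libraries between 41 (without the vector library of clone 12) and 889 (without the NR6A1 library of clone 6).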

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

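The tests of explanations in this section bear on results found in the same data, so they were chosen after those results were seen. Several gene groups moved one way with NR6A1 in clone 6 and the other way in clone 12, and none of these differences between clones was tested, since 1 library per clone and virus leaves no degree of freedom for it. Interferon response genes had a median log2 change of 0.814 in clone 6 and -0.141 in clone 12: 31 of 38 were higher in clone 6 and 32 of 38 lower in clone 12. Their level was higher in clone 12 than in clone 6 by a median of 2.52 log2 units with vector and 1.49 with NR6A1. Inflammatory and NF-kB genes had medians of 0.137 and -0.109, and glycolysis and hypoxia genes 0.124 and -0.175. Apart from short RNA genes, 7 genes changed by at least 1 log2 unit in opposite directions in the clones, among them 1700029I15Rik, AI316807, Atp6v1c2, Gngt2, Nnat and Utp14b.

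The 3 short RNA genes past the threshold, Snord72, Mir1907 and Snord91a, were listed at 0 in one group and had nearly the same value in both libraries of the other. Equal numbers of reads in both libraries give values in the inverse ratio of the depths, and in 3 of the 3 genes the observed ratio was within 2% of it (1.029 against 1.029, 1.028 against 1.029 and 1.045 against 1.06). A gene at 0 in one group passes this test only if its other 2 values are nearly equal. As the depth ratios are also near 1, the match was largely fixed beforehand and cannot show equal read numbers. Among 24 other short RNA genes above 0 in exactly 2 libraries, 10 met the same bound. A different set held the 24 tested short RNA genes above 0 in exactly 2 libraries, the 3 calls among them. Of this set, 20.8% (exact 95% interval 7.13% to 42.2%) were in both libraries of one virus, against 33.3% by chance. No excess of virus-specific genes was thus seen. By number, 5 were in both libraries of one virus, 11 in both of one clone and 8 in libraries of different virus and clone. The 3 calls may be small numbers of reads that fell by chance in libraries of one virus. An effect of NR6A1 on them stays open and was not tested.

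The higher level of smooth muscle and contractile genes with NR6A1 was set against a GC or length trend and against an effect of 1 clone. With the trend removed the list's median log2 change was 0.26, close to the 0.295 before, which argues against that trend as the whole cause. The median was 0.312 in clone 6 and 0.257 in clone 12, so the rise was not limited to 1 clone. The smaller median lay above all 10000 random lists of matched expression. Random lists do not allow for genes that move together, so this decides nothing. Interferon response genes lay above all random lists in clone 6 and below all in clone 12. The expression of NR6A1 may raise these genes, a hypothesis found and tested on the same 4 libraries, and differences in cell density or spreading between cultures stay open and were not tested.

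The lower level of cholesterol synthesis genes was weighed in the same way. With the GC and length trend removed the median was -0.3219 against -0.320 before, which argues against that trend as the whole cause. The median was -0.315 in clone 6 and -0.224 in clone 12, so the fall was not limited to 1 clone. The smaller change lay below all 10000 random lists, which have the limit given above. The list falling in both clones is in line with an effect of NR6A1 as a hypothesis; differences in medium, serum or density at harvest stay open and were not tested.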

How the results depend on the processing

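The removal of short RNA genes, of a GC and length trend and of Nr6a1 from its list were chosen after seeing the data. Genes changed by NR6A1 (4; 3 higher, 1 lower) numbered 25 at a false discovery rate of 0.1. They numbered 7 with a pseudocount of 5 (4 lower), 2 with no filter (0 lower), 38 with a robust prior (10 higher, 28 lower) and 52 without short RNA genes (10 higher, 42 lower); with a pseudocount of 0.1, 3 were lower. The prior of limma rose from 2.9 to 4.43 degrees of freedom without short RNA genes and fell to 1.7 with no filter; otherwise the cause was not tested. Genes differing between clones (2490) numbered 0 with no filter (5360 at an unadjusted p under 0.05) and 1581 without a trend. Lists past the threshold (5) numbered 3 with no filter, where osteoblast genes and p53 targets were lost. Genes shared by both clones (60 at 2-fold) numbered 165 at 1.5-fold, 106 with a pseudocount of 0.1 and 24 with one of 5. Without the clone block, so without the pairing, 4 genes were called as with it, while genes at an unadjusted p under 0.05 fell from 962 to 156; osteoblast genes (adjusted p = 0.371) and p53 targets (0.0631) lost their call and fibroblast markers gained one (0.0288); it changed no other list or gene call. The upper quartile and quantile scalings put the median log2 change of all genes at -0.00287 and 0.0101 (0.000985 in the main fit) and left 4 calls.

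With each library left out in turn the clone block could not be kept, so clone differences mix with those of virus, and the lone library is assumed to vary like the others. Then limma called 0 genes (0 higher, 0 lower; 96 to 286 at an unadjusted p under 0.05), Nr6a1 changed by 7.047 to 7.492, 41 to 889 genes differed between clones and 8 to 12 lists passed. Where a list turned direction and was called in the main or the reduced fit, its median over the 4 fits ran from -0.6441 to 0.7592 (osteoblast), 0.03223 to 0.5511 (contractile, where camera's direction turned without the vector library of clone 12), -0.834 to 1.412 (interferon), -0.5577 to 0.4886 (inflammatory), -0.2475 to 0.1708 (glycolysis) and -0.3602 to 0.6861 (immediate early); cholesterol synthesis genes kept direction and call in all 4, with medians from -0.4532 to -0.1118. Other list values, 23 in all, turned direction without a call in the main or that fit. Over the 4 fits the medians of such lists ran from -0.3587 to 0.2372 for Wnt, -0.2987 to 0.1597 for TGF-beta and BMP, -0.3556 to 0.6109 for chondrocyte, -0.1967 to 0.2124 for limb bud, -0.1149 to 0.1903 for imprinted and -0.06051 to 0.5067 for skeletal muscle genes. Of 112 list values in these fits 53 kept direction and side of the threshold, 23 newly passed, 4 no longer passed and 9 turned with a call. Those that newly passed were of the let-7, Hox, imprinted, fibroblast, matrix, matrix protease, interferon, inflammatory, TGF-beta, Wnt, glycolysis, oxidative stress, limb bud, ribosomal and skeletal muscle lists. The let-7 list held Nr6a1 itself in these fits. Of 592 values of named genes 432 kept both, 144 turned direction without passing and 16 no longer passed.

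Of 1602 values of named genes under settings with all 4 libraries, 1569 kept direction and side of the threshold, 27 newly passed, 2 no longer passed and 4 turned direction without passing; of 307 list values, 297 kept both, 2 newly passed, 5 no longer passed and 3 turned direction without passing. The highest value of a repeated symbol was not run, since no symbol repeats. At the inferred depth, values of short RNA genes rest on few reads.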

Other observations

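Beyond the genes named so far, these others of the 52 found without short RNA genes were named after their values were seen. Nrn1, a membrane-anchored neurite growth protein gene, was at 168 and 191 FPKM in the vector libraries of clone 6 and clone 12 and at 72.3 and 62.1 in the NR6A1 libraries (log2 change -1.41 ± 0.12, SE). Igfbp7, a secreted growth factor binding protein gene, was at 248 and 291 against 91.1 and 151 FPKM (-1.19 ± 0.14). The calcium-binding protein gene S100a16 changed by -1.98 ± 0.17, the potassium channel domain gene Kctd12 by -1.70 ± 0.09, the complement protease gene Masp1 by -1.78 ± 0.17 and the chemokine gene Cxcl14 by -1.42 ± 0.17. The oxygen carrier gene Mb was at 2.99 and 3.15 FPKM with vector, and at 0 and 0.0624 with NR6A1.

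Within lists that did not pass as a group, single members passed adjusted over the list alone. Of the Wnt pathway genes, Sfrp2, Wnt10b, Wnt5a and the transcription factor gene Tcf7 were lower and Dkk3 and the receptor gene Fzd1 higher. Among mesenchymal markers Ly6a was lower, and the adhesion genes Alcam (0.59 ± 0.10) and Mcam (0.62 ± 0.10) and the growth factor receptor gene Pdgfra (0.53 ± 0.11) were higher. The matrix genes Postn (1.24 ± 0.24), Nid2 (0.93 ± 0.15) and Col3a1 were higher and Col8a1 (-1.29 ± 0.20), Loxl3 and Thbs2 lower, and in the TGF-beta list Tgfb2 was lower (-1.55 ± 0.26). These genes were named after their values were seen, and apart from those among the 52 they passed only within their lists.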
